A study of Mus musculus with 20 samples.

How the data were processed

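The deposited files held 1 table of raw read-pair counts per library, for 55,573 genes, with 5 closing lines for read pairs given to no gene. The submitters name FastQC 0.11.8, cutadapt 2.1, STAR 2.7.1a, HTSeq 0.11.2 and DESeq2, without a DESeq2 version, and the mouse build GRCm38. cDNA was made with a SMART-Seq v4 kit and libraries with Nextera XT, which keep no strand information, and they were sequenced as read pairs on a NovaSeq6000. The HTSeq counting mode and what was merged in files named as merged are not given in the sources used here. A further label speaks of total RNA depleted of ribosomal RNA, which a SMART-Seq v4 protocol does not involve, and the labels do not say which step that refers to. Raw reads were not used here.

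Gene symbols, positions and types came from GENCODE M21 for GRCm38, which matched 55,480 of the gene identifiers. Counts stood on their original scale, and values per gene are given in CPM, counts relative to library size, with sizes scaled by edgeR's TMM factors. Because reads carried no strand and were counted per gene, counts of genes with near-identical copies or overlapping neighbours are uncertain, which among the genes named below holds for Tgtp1 and Tgtp2, the guanylate-binding proteins and the alpha and beta globins. The plan took Leprot and Lepr to share first exons, but in GENCODE M21 the genes do not overlap, so no read pair counted for both.

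Group differences were tested in edgeR 4.0.16 with quasi-likelihood F tests on all 20 libraries (TMM, filterByExpr with a minimum count of 10 and a minimum total of 15, robust dispersion, group as the only term), and p-values were adjusted by the Benjamini-Hochberg method over 16,509 genes with a threshold of 0.05. All tests are two-sided, log2 fold changes carry the fitted standard error (SE), and CPM carry the SD over 5 libraries. The biological coefficient of variation was 0.747. The groups, contrasts, gene lists, naming rule and most alternatives were set before the data were examined. The p-values measure the spread between these samples, which came from pools of 2 mice. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Where all libraries of a group had 0 counts, a fold is given as a bound against 3 counts over the group, and where a group held 1 to 3 counts, as a ratio with its 95% exact binomial interval. The fitted fold changes of such genes depend on the prior count and are not bounds. For other genes the printed fold changes are the fitted ones.

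There were 33 fixed gene lists, of which 31 were tested with limma camera (limma 3.58.1) on log2 CPM with a prior count of 2 and the preset inter-gene correlation of 0.01, adjusted over the 31 lists within a contrast. They covered stem cell identity, megakaryocyte and platelet, lymphoid priming, granulocyte-monocyte progenitor, erythroid, S phase, G2/M phase, quiescence, type I interferon, interferon gamma, TNF and NF-kB, cytokine receptors, MHC class II, immediate early and stress, leptin and JAK-STAT, p53 targets, homing and adhesion, fetal stem cell, oxidative phosphorylation, glycolysis and hypoxia, fatty acid oxidation, mitochondrially encoded, ribosomal protein, and markers of stromal, endothelial, neutrophil, monocyte and macrophage, B, T and NK, mast and basophil, and dendritic cells. The lists of sort antigens and sex-linked genes were read as levels only. Camera calls were repeated with a correlation estimated for each list, because correlated genes make the preset value lenient. A list whose call was lost is given with both values. Counts of list members past 0.05 are given over all genes and adjusted over the list alone.

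Genes were named by a rule. It took the 10 largest rises and the 10 largest falls at an adjusted p under 0.05, with a mean of at least 5 CPM in the higher group and the same sign in at least 4 of the 5 replicate pairs, leaving out predicted, clone and receptor segment names. It added up to 4 members of each list by smallest p, and always Lepr, Leprot, Slamf1, Cd48, Ly6a, Kit and Xist. Genes named outside it were chosen after their values were seen, which below holds for the levels of Cxcl12, Col1a1 and other marker genes printed as CPM without a fold change. The lists by month and without single libraries were also read after the first results were seen.

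The design text gives 2 mice for each of 5 replicates and the protocol 2 mice per sample, and each replicate number carried 1 date in June or July in all 4 groups, so the number was read as 1 pool of mice that pairs the libraries. In a check on deviations from the group means, the 30 pairs of libraries with the same number correlated at a median of 0.264 (range -0.065 to 0.562) and the 120 pairs with different numbers at -0.086, and 14 of 20 libraries lay closest to their own number. Pairs of replicates 1, 3 and 4 ran from 0.19 to 0.562, but those of replicate 2 from -0.065 to 0.18 and of replicate 5 from 0.037 to 0.145. Deviations within a group sum to 0, so the value for different numbers falls as that for the same number rises. As the number also goes with the date, the check cannot show that a number is 1 pool of mice. Fits with the number as a block are given beside the results where they change a call or move a count by more than 1.5 times. June held replicates 1, 3 and 5 and July replicates 2 and 4, each with all 4 groups.

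A self-test drew simulated counts for all 20 libraries, gene by gene, from the means and dispersions of the block fit. Known changes were put into Lepr+ HSC. The fit without the block recovered 61% of 4-fold and 7% of 2-fold changes, with 1 false call among 69. With the block, whose model made these counts and which is thereby favoured, 72% and 35% were recovered, with 4 false calls among 111. Camera gave an unadjusted p of 1.34e-10 for a seeded list and an unadjusted p under 0.05 for 1 of 100 random lists. As the simulated genes did not correlate, that rate does not describe camera calls on correlated genes. Fits ran in R 4.3.3, with DESeq2 1.42.0 among the alternatives, and figures in Python 3.11.15 with matplotlib 3.10.9.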

Results

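RNA was measured in haematopoietic stem cells (HSC) and multipotent progenitors (MPP) of C57BL/6 mouse bone marrow, each sorted with or without leptin receptor protein (Lepr) on the cell surface. The question was what sets apart the stem cells and progenitors that carry the receptor for leptin, the hormone through which fat tissue signals energy stores. All cells came from the gate that lacks lineage antigens and carries Sca-1 and c-Kit. HSC were taken as CD150+CD48- cells and MPP as CD150-CD48- cells. Each of the 4 groups had 5 libraries, made from 1,000 to 8,000 cells of 2 mice per sample. Libraries held between 9,532,993 and 31,589,794 counts in genes. At an equal depth of 9,532,993 counts, 14,756 to 20,788 genes had a count. The libraries least like their own group were Lepr+ MPP replicate 4 (mean correlation 0.815 with its group), Lepr+ HSC replicate 5 (0.837) and Lepr+ MPP replicate 5 (0.858), and each comparison was repeated without these 3. Xist was read in all 20 libraries, and no Y-linked gene passed 0.04 CPM in any.

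Transcripts of Lepr itself were rare in the sorted stem cells and uneven between libraries. Mean Lepr was 0.0448 ± 0.0718 CPM in Lepr- HSC and 3.66 ± 4.60 CPM in Lepr+ HSC (SD, n = 5 here and for all CPM below). It was 0.275 ± 0.380 CPM in Lepr- MPP and 23.3 ± 14.6 CPM in Lepr+ MPP. Lepr+ HSC replicates 1 to 5 had 0.356, 0.514, 7.98, 0.0759 and 9.36 CPM, and Lepr+ MPP replicates 1 to 5 had 0.261, 27.1, 30.5, 38.8 and 19.7 CPM. Among Lepr- libraries the values ran from 0 to 0.165 CPM in HSC and from 0 to 0.767 CPM in MPP. Of the Lepr counts in Lepr+ HSC, replicate 3 held 275, and replicate 4 had 1 against 0 in its Lepr- pair. Lepr was higher in 5 of 5 pairs of HSC, where 384 counts stood against 3, a ratio of 123 (41.6 to 597), and in 4 of 5 pairs of MPP. It passed in neither over all genes (adjusted p = 0.204 and 0.145, with a log2 fold change of 6.41 ± 1.62 in MPP). Adjusted over the list alone, the sort antigens Lepr and Ly6a were higher in Lepr+ HSC and Lepr in Lepr+ MPP. Leprot, the neighbouring gene whose product controls receptor traffic to the surface, stood at 97.4 ± 13.97 and 108.3 ± 20.4 CPM in Lepr- and Lepr+ HSC and at 95.8 ± 24.97 and 90.0 ± 15.1 CPM in the MPP groups.

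Of the other sort antigens Slamf1, which encodes CD150, followed the gates, with 46.6 ± 13.4 CPM in Lepr- HSC against 5.12 ± 3.83 CPM in Lepr- MPP. Both gates lack CD48, yet Cd48 had 14.3 ± 6.59 CPM in the same HSC against 50.6 ± 16.1 CPM in the MPP. Kit, the stem cell factor receptor, stood between 562 ± 195 CPM in Lepr- HSC and 883.1 ± 166.9 CPM in Lepr- MPP. Slamf1, Cd48, Kit and Xist did not pass between Lepr+ and Lepr- cells of either type, with adjusted p from 0.707 to 1. Cxcl12, a chemokine that marrow stromal cells make in large amounts, had 1.80 ± 3.56, 30.8 ± 27.5, 1.15 ± 1.12 and 330.9 ± 212.1 CPM in Lepr- HSC, Lepr+ HSC, Lepr- MPP and Lepr+ MPP. On GRCm38, Lepr (ENSMUSG00000057722.17) lies on chromosome 4 from 101717404 to 101815352, Leprot (ENSMUSG00000035212.14) on the same strand from 101647718 to 101659364, and Slamf1 and Cd48 next to each other on chromosome 1 from 171767127 to 171801184 and from 171682009 to 171705258.

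**Figure D1:**
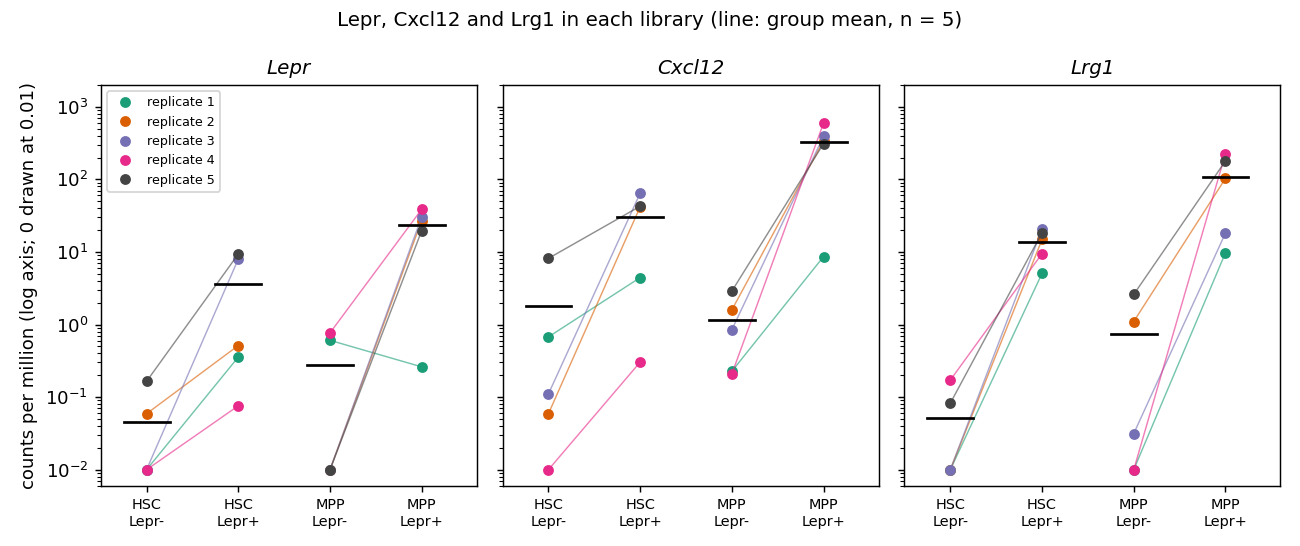
CPM of Lepr, Cxcl12 and Lrg1 in each of the 20 libraries on a log axis, with 0 drawn at 0.01 and a line at each group's mean. Lepr ran from 0.0759 to 9.36 CPM in Lepr+ HSC and from 0.261 to 38.8 CPM in Lepr+ MPP, and mean Cxcl12 was 30.8 and 330.9 CPM in these groups.

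Lepr+ HSC carried more mRNA of stem cell genes than Lepr- HSC. Procr, the endothelial protein C receptor that marks long-term stem cells, rose from 30.9 ± 11.03 to 99.2 ± 27.3 CPM. Hlf, a transcription factor that maintains stem cells, rose from 153.7 ± 37.3 to 325.5 ± 46.8 CPM. Nkx2-3, a homeobox factor, rose from 29 ± 6.84 to 76.8 ± 15.7 CPM. Genes of antigen presentation and of the interferon gamma response were higher as lists. Among Lepr- cells, however, Hlf (-1.42), Ly6a (-1.27) and these lists (medians -0.70 and -0.69) were lower in HSC than in MPP. The stem cell list was higher in HSC there (median 0.65), a call lost with an estimated correlation (adjusted p = 0.0731). Erythroid and megakaryocyte genes stood lower with the preset correlation only (adjusted p = 0.112 and 0.190 with an estimated correlation). Over all genes edgeR called 17, of which 16 rose and 1 fell.

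Among the called genes, log2 fold changes were 1.68 ± 0.26 for Procr (adjusted p = 0.0120), 1.08 ± 0.17 for Hlf (adjusted p = 0.0120) and 1.40 ± 0.20 for Nkx2-3 (adjusted p = 0.0120), each higher in 5 of 5 pairs. Nceh1, a cholesterol ester hydrolase, rose by 1.20 ± 0.18 and Ltb, the membrane anchor of lymphotoxin, by 1.57 ± 0.28. Vegfc, a growth factor of lymphatic vessels, rose by 1.59 ± 0.29 and Irf9, the DNA-binding subunit of the type I interferon signal, by 0.87 ± 0.17 (adjusted p from 0.0120 to 0.0411). Lax1, an adaptor of lymphocyte receptor signalling, rose by 1.64 ± 0.31 and Tmem71 by 1.54 ± 0.28. Gas6, a ligand of the Axl family of receptors that also stands in the stromal list, rose from 6.24 ± 3.79 to 28.6 ± 10.2 CPM (adjusted p = 0.0347). Lrg1, a secreted glycoprotein known from blood vessels, went from 3 to 1428 counts, a ratio of 456 (156 to 2210). Gpm6a, a membrane glycoprotein best known from neurons, went from 2 to 680 counts, a ratio of 325 (89.7 to 2690), both with an adjusted p of 0.0266 and higher in 5 of 5 pairs. Rabgap1l, a regulator of Rab GTPases, was the gene that fell (-1.03 ± 0.17, adjusted p = 0.0145, lower in 5 of 5 pairs). Procr (ENSMUSG00000027611.12) lies on chromosome 2 from 155751117 to 155755471 and Hlf (ENSMUSG00000003949.16) on chromosome 11 from 90336536 to 90390895. Nkx2-3 (ENSMUSG00000044220.13) lies on chromosome 19 from 43612325 to 43615892, Lrg1 (ENSMUSG00000037095.8) on chromosome 17 from 56119678 to 56122001 and Gpm6a (ENSMUSG00000031517.8) on chromosome 8 from 54954843 to 55060871.

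Of the 25 measured genes of stem cell identity, 2 rose over all genes and 7 rose and 1 fell adjusted over the list alone. Among them Procr, Hlf, Ndn and Ly6a moved up. The list stood higher by a median log2 of 0.67 (adjusted p = 1.62e-08, and adjusted p = 0.00548 with an estimated correlation, higher in 5 of 5 pairs). With replicate number as a block 7 of its genes rose and 1 fell. They included Ly6a, the gene of Sca-1 (1.33 ± 0.33, adjusted p = 0.129 without and 0.00314 with the block), and Ndn, a cell cycle inhibitor (1.00, adjusted p = 0.0980 and 0.0113). Of the 11 genes of MHC class II presentation 0 rose over all genes, 5 rose with the block and 6 rose adjusted over the list alone. The list median was 0.89 (adjusted p = 3.70e-08, and 0.00209 with an estimated correlation, 5 of 5 pairs). H2-Aa had 35.01 ± 12.01 and 113.2 ± 55.1 CPM in Lepr- and Lepr+ HSC (1.69 ± 0.38, adjusted p = 0.0980 and with the block 0.00332). H2-Ab1 gave 0.89 ± 0.18 (adjusted p = 0.0685 and 0.00909) and Cd74, the class II chaperone, had 39.4 and 116.1 CPM. Genes of antibody-making cells had higher means too, unevenly. Igkc had 0.261 CPM in Lepr- HSC and 106.6 ± 153.6 CPM in Lepr+ HSC (adjusted p = 0.144, and 0.04975 with the block). Jchain had 1.08 and 48.1 ± 90.0 CPM (adjusted p = 0.415, and 0.154 with the block), each higher in 4 of 5 pairs. The lists of B cells (adjusted p = 0.971) and dendritic cells (adjusted p = 0.853) did not pass. Of the 31 genes of the interferon gamma response 0 passed over all genes, 5 rose with the block and 8 rose adjusted over the list alone. Among them were the GTPases Tgtp1 (1.21, adjusted p = 0.0685 and 0.00435 with the block) and Igtp (0.86, adjusted p = 0.115 and 0.0261). Its median was 0.56 (adjusted p = 6.13e-06, and 0.00561 with an estimated correlation, 4 of 5 pairs).

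TNF and NF-kB targets stood higher by a median of 0.37 (adjusted p = 0.000106, and 0.00548 with an estimated correlation). Of 27 members 1 rose over all genes, Ltb, and 6 adjusted over the list alone. Cytokine receptors stood higher by 0.45 (adjusted p = 0.000104, and 0.0105 with an estimated correlation). Of 23 members 0 passed over all genes and 4 adjusted over the list alone, Il21r, Tnfrsf1b, Tlr2 and Ifngr2. Genes of red cells stood lower by a median of -1.50 (adjusted p = 1.66e-05, lower in 5 of 5 pairs), a call lost at an adjusted p of 0.112 with an estimated correlation. None of its 19 members passed. Gata1, the master factor of red cells and megakaryocytes, had 184.3 ± 67.2 and 64.9 ± 40.4 CPM (adjusted p = 0.528), and Car1 232 and 27.8 CPM (adjusted p = 0.442). Megakaryocyte and platelet genes stood lower by a median of -0.70 (mean -0.01, adjusted p = 0.00487, and adjusted p = 0.190 with an estimated correlation). Of 19 members 0 passed over all genes, and 1 was higher and 4 lower adjusted over the list alone. With the block Pf4, platelet factor 4, fell (1857 ± 970 to 467.2 ± 214.3 CPM, adjusted p = 0.2496 without and 0.00366 with it), as did Itga2b (-1.37, adjusted p = 0.191 and 0.0113). The lists of S phase (-0.48, adjusted p = 1.62e-08) and of G2/M phase (-0.65, adjusted p = 3.70e-08) stood lower in 5 of 5 pairs, both lost at adjusted p of 0.0640 and 0.0960 with an estimated correlation.

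Of the marker lists of other marrow cells, only the stromal and endothelial ones were called, with the preset correlation only. The stromal list stood higher in Lepr+ HSC by a median of 1.86 (adjusted p = 1.64e-06 and 5 of 5 pairs, but adjusted p = 0.159 with an estimated correlation). Of its 24 genes 1 passed over all genes and 7 adjusted over the list alone. The endothelial list stood higher by 1.05 (adjusted p = 0.000275, and 0.159 with an estimated correlation). With the mean of both lists as a covariate 6 genes were called, and 63 with the block as well. Genes of both lists make up this mean, so a loss of their own calls with it tests nothing. The lists of quiescence (0.36, adjusted p = 0.00108), type I interferon (0.43, adjusted p = 1.53e-05), granulocyte and monocyte progenitors (0.71, adjusted p = 0.0342, and 0.0560 with the block), homing (0.25, adjusted p = 0.00267), fetal stem cells (1.08, adjusted p = 0.00364) and oxidative phosphorylation (-0.29, adjusted p = 0.00160) were called with the preset correlation only. They had adjusted p from 0.117 to 0.667 with an estimated correlation. The other 14 lists had adjusted p from 0.120 to 0.971, and for neutrophil, monocyte, B cell and mast cell markers the median, mean and test differed in sign.

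The count of genes rested on few libraries, with 0 called by edgeR without Lepr- HSC replicate 2, Lepr- HSC replicate 3 or Lepr+ HSC replicate 5 (1043, 1027 and 1094 at an unadjusted p under 0.05). It was 3 without Lepr- HSC replicate 5, 11 without Lepr- HSC replicate 4 and 8 without the 3 libraries least like their groups. Without replicate numbers 2, 3, 4 or 5 in all groups it was 0 (812, 788, 1395 and 923 at that level). Over all libraries DESeq2 called 181 and limma voom 10. With the block 169 genes were called (126 up and 43 down), the 17 among them, and 23 to 88 without 1 replicate number in all groups. In June alone edgeR called 0 genes (1031 at an unadjusted p under 0.05) and in July alone 0 (426), against 1149 at that level over all 5 pairs. The 5 lists that held with an estimated correlation kept their direction and preset call in both months, but with an estimated correlation only 1 was called in June and 0 in July.

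**Figure D2:**
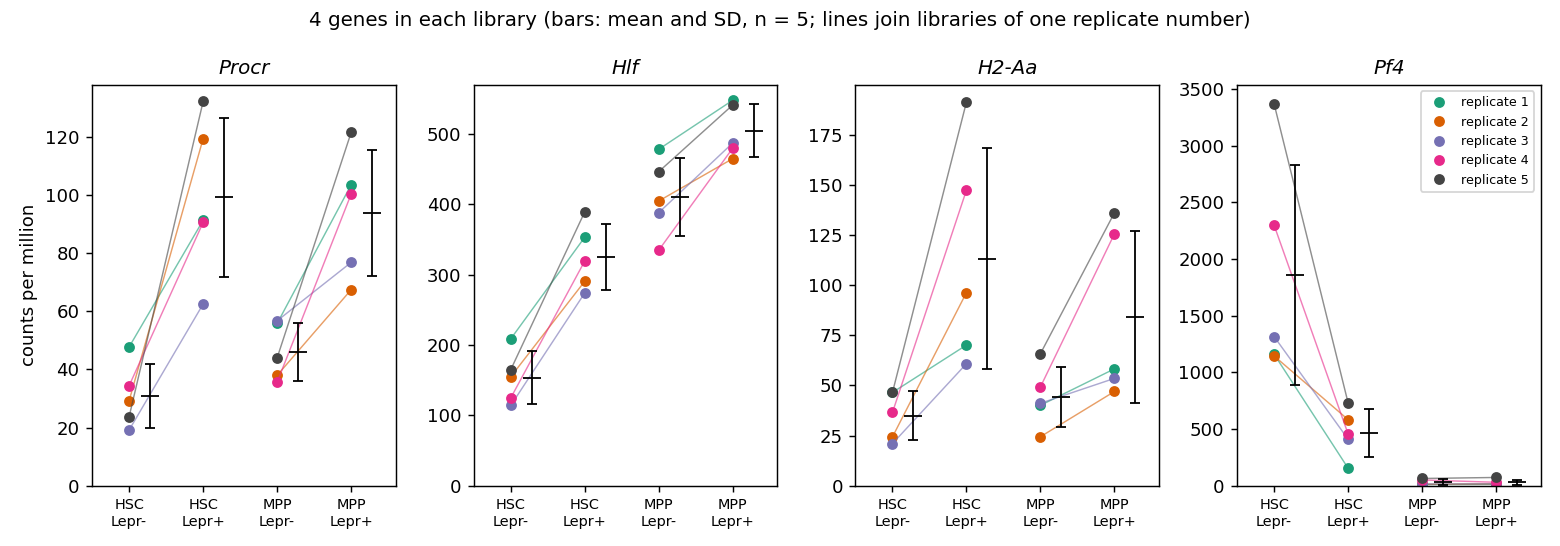
CPM of Procr, Hlf, H2-Aa and Pf4 in each library by group, with the mean and SD of 5 libraries. Procr rose from 30.9 to 99.2 CPM and Hlf from 153.7 to 325.5 CPM between Lepr- and Lepr+ HSC, and Pf4 stood at 1857 and 467.2 CPM there and at 31 and 30.3 CPM in the MPP groups.

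Lepr+ MPP differed from Lepr- MPP most of all in genes of marrow stroma and blood vessels. Adipoq, the hormone adiponectin that marrow stromal cells and fat cells make, had 0 counts in Lepr- MPP and 25.1 ± 15.3 CPM in Lepr+ MPP, at least 745-fold more. Fabp4, a fatty acid carrier of capillaries and fat cells, rose from 0.945 to 99.7 ± 112.6 CPM, and Gata1 fell from 60.4 ± 35.96 to 6.87 ± 5.60 CPM. EdgeR called 33 genes, of which 29 rose and 4 fell. With the block it called 17, among them Fabp4 but not Adipoq or Gata1. The stromal signal was uneven. In mean log2 CPM of the stromal list Lepr+ MPP replicate 1 had 1.736 and the other libraries of its group 4.15 to 5.506. Lepr- MPP libraries had -0.562 to 0.116. Whether the stromal and vessel RNA came from the sorted MPP or from other marrow cells in the samples was not tested.

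Of the 24 stromal genes 9 rose over all genes and 21 adjusted over the list alone. The median log2 was 7.90, or 7.15 with 8 genes at their bounds (adjusted p = 3.88e-43, and 0.00155 with an estimated correlation, 5 of 5 pairs). The matrix genes Dcn (1710 counts against 1, a ratio of 1790, 322 to 70900) and Col3a1 (3307 against 3, a ratio of 1160, 395 to 5610) rose with an adjusted p of 0.0384. Col1a2 rose from 13.5 ± 5.93 to 235 ± 347 CPM (4.12 ± 0.75, adjusted p = 0.0339), and Igfbp5, a binding protein of insulin-like growth factors, by 9.48 ± 1.62 (adjusted p = 0.0253). Esm1, a proteoglycan of vessel tips, rose with 991 counts against 1, a ratio of 1040 (186 to 41100, adjusted p = 0.0384). Of the 18 endothelial genes 3 rose over all genes and 10 adjusted over the list alone. Their median was 3.20 (adjusted p = 7.72e-18, and 0.00381 with an estimated correlation, 5 of 5 pairs). These were Fabp4 (6.70 ± 0.96, adjusted p = 0.00796), Sox18, a vessel transcription factor (3.24 ± 0.63, adjusted p = 0.0384), and Cdh5, the cadherin of endothelial junctions (1000 counts against 2, a ratio of 524, 145 to 4340, adjusted p = 0.0433). Outside these lists rose Aplnr, the apelin receptor of vessels (1833 counts against 2, a ratio of 961, 266 to 7940, adjusted p = 0.00796). So did Fbln5 and Kcnj8 (at least 1030-fold and 520-fold higher, adjusted p = 0.0384 and 0.0366), Cyp1b1 (a ratio of 1350, 241 to 53200, adjusted p = 0.0384) and Chrdl1 (a ratio of 1280, 230 to 50800, adjusted p = 0.0339, 4 of 5 pairs), the others in 5 of 5 pairs but for Col3a1 in 4. Clu, a secreted chaperone held by the megakaryocyte list, rose by 3.56 ± 0.73 (adjusted p = 0.0463), while that list did not pass (adjusted p = 0.466). Of the genes named in this paragraph, Dcn, Igfbp5, Fabp4, Aplnr and Clu kept their calls with the block and the others lost them.

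Red cell genes stood lower in Lepr+ MPP by a median of -1.45 (adjusted p = 8.64e-11, and 0.0199 with an estimated correlation, lower in 5 of 5 pairs). Gata1 was the 1 of 19 that fell (-3.14 ± 0.63, adjusted p = 0.0433, and 0.0612 with the block). Adjusted over the list alone 4 were lower, Gata1, Klf1, Rhd and Car1. Pklr, the pyruvate kinase of liver and red cells, fell from 913 counts to 1, a ratio of 870 (156 to 34400, adjusted p = 0.0384, 5 of 5 pairs). The stem cell list stood higher by a median of 0.55 (adjusted p = 2.95e-08, and 0.00687 with an estimated correlation, 5 of 5 pairs). Its 1 member past the threshold over all genes was Gpx3, a secreted glutathione peroxidase made by many tissues (5.20 ± 1.02, adjusted p = 0.0384, and 0.113 with the block). Adjusted over the list alone Gpx3, Ndn, Procr and Sult1a1 rose. Procr had 46.0 ± 9.84 and 93.9 ± 21.7 CPM (1.03, adjusted p = 0.136, 5 of 5 pairs). The MHC class II list stood higher by 0.44 (adjusted p = 0.000874, and 0.0259 with an estimated correlation, 5 of 5 pairs). Of its 11 genes 0 rose over all genes, 1 with the block, Cd74 (1.69 ± 0.45, adjusted p = 0.180 and 0.00903), and 2 adjusted over the list alone. Beside them Igkc had 0.355 and 864.7 ± 1513 CPM (adjusted p = 0.0587, and 0.0360 with the block). Jchain had 0.239 and 253 ± 363 CPM. With the stromal and endothelial mean as a covariate the stem cell and class II lists had medians of 0.39 and 0.42 (adjusted p = 0.0121 and 0.0271, and 0.340 and 0.336 with an estimated correlation as well). With genes detected at equal depth as a covariate the red cell and class II lists had medians of -1.80 and 0.45, with adjusted p of 0.0559 and 0.0514 with an estimated correlation.

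Called with the preset correlation only were the lists of lymphoid priming (-0.66, adjusted p = 0.0144), S phase (-0.42, adjusted p = 9.08e-09), G2/M phase (-0.33, adjusted p = 0.000112), fetal stem cells (1.04, adjusted p = 0.0154), mitochondrially encoded genes (0.77, adjusted p = 0.00947), monocytes and macrophages (0.98, adjusted p = 2.71e-05) and T and NK cells (-1.20, adjusted p = 0.000910). They had adjusted p from 0.0706 to 0.426 with an estimated correlation. Mitochondrially encoded genes turned direction without the 3 libraries least like their groups (adjusted p = 0.0351), of which Lepr+ MPP replicates 4 and 5 had 3.03% and 4.46% of counts in them. Fetal and monocyte genes turned direction with the covariate (adjusted p = 0.857 and 0.189). Dntt, the terminal transferase of early lymphocytes, had 152.2 ± 100.7 CPM in Lepr- MPP and 10.9 ± 5.65 CPM in Lepr+ MPP (adjusted p = 0.164, lower in 5 of 5 pairs). The other 19 lists had adjusted p from 0.0570 to 0.964, of which quiescence, interferon gamma and glycolysis passed with the block (adjusted p = 0.0495, 0.0495 and 0.0442). For type I interferon, TNF, cytokine receptor, p53, homing, oxidative phosphorylation, fatty acid oxidation, neutrophil, B cell and dendritic lists the median, mean and test differed in sign.

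With the block edgeR called 17 genes, of which 11 were among the 33, and ended the calls of Fbln5, Adipoq, Kcnj8, Esm1, Cyp1b1, Col3a1, Chrdl1, Gpx3, Col1a2, Sox18, Cdh5 and Gata1 (adjusted p from 0.05003 to 0.113). Without 1 library it called 4 (Lepr- MPP replicate 1, 2 or 3), 5 (Lepr- MPP replicate 4 or Lepr+ MPP replicate 5), 6 (Lepr+ MPP replicate 2), 9 (Lepr+ MPP replicate 4), 11 (Lepr- MPP replicate 5), 15 (Lepr+ MPP replicate 3), 16 (Lepr- HSC replicate 1) or 20 (Lepr- HSC replicate 4). Without replicate numbers 1 to 5 in all groups it called 12, 0, 0, 5 and 1, with 613 and 554 at an unadjusted p under 0.05 where it called 0. The block fit then called 0 to 11. Over all libraries DESeq2 called 213 and limma voom 304. June alone gave 0 genes (556 at an unadjusted p under 0.05), July alone 0 (367) and the 5 pairs 728. The 5 lists that held kept their direction and preset call in both months, with 1 called in June and 0 in July with an estimated correlation. With an estimated correlation the red cell list was lost without Lepr+ MPP replicate 1, 2 or 3 or Lepr- MPP replicate 4 (adjusted p = 0.115, 0.0612, 0.0857 and 0.0523). The class II list was lost without Lepr+ MPP replicate 1 or 4 (adjusted p = 0.0640 and 0.107). Without the 3 libraries least like their groups edgeR called 0 genes (793 at an unadjusted p under 0.05), and with the covariate 1, which was not among the 33. The covariate takes out stromal and endothelial genes by its make-up.

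Among Lepr- cells, HSC differed from MPP by megakaryocyte genes that were higher and by lymphoid, MHC class II and interferon gamma genes that were lower. Pf4 stood at 1857 ± 970 CPM in HSC and 31 ± 24.99 CPM in MPP, and Vwf, the von Willebrand factor of platelets and vessels, at 454.5 ± 198 and 12.9 ± 9.55 CPM. Flt3, the cytokine receptor of multipotent and lymphoid progenitors, fell from 473.9 ± 147.4 CPM in MPP to 19.9 ± 12.7 CPM in HSC, and Cd34 from 1146 ± 204 to 192 ± 12.7 CPM. Genes of DNA replication and mitosis were higher in HSC. EdgeR called 451 genes, of which 201 were higher in HSC and 250 lower.

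Of the 19 megakaryocyte genes 11 were higher in HSC over all genes and 16 adjusted over the list alone. The median log2 was 2.33 (adjusted p = 1.05e-21, and 0.000552 with an estimated correlation). Pf4 rose by 5.91 ± 0.69 (adjusted p = 6.92e-05), Vwf by 5.14 ± 0.55 (adjusted p = 2.66e-05) and Itga2b, the platelet integrin, by 2.96 ± 0.39 (adjusted p = 0.000176), each in 5 of 5 pairs. Cavin2, a protein of caveolae abundant in platelets, rose by 5.70 ± 0.84 and the phosphodiesterase Pde10a by 7.80 ± 1.30 (adjusted p = 0.000503 and 0.00140). Of the 18 lymphoid genes 6 were lower and 1, Mef2c, higher over all genes, and 12 lower and 1 higher adjusted over the list alone (median -2.92, adjusted p = 4.89e-12, and 0.0115 with an estimated correlation). Dntt fell by 7.85 ± 1.22 (adjusted p = 0.000791), Flt3 by 4.57 ± 0.74 (adjusted p = 0.00112) and Cd27, a receptor of the TNF receptor family, by 1.59 ± 0.21 (adjusted p = 0.000176). Cd34 fell by 2.58 ± 0.18 (adjusted p = 1.02e-07) and the secreted protein gene Wfdc17 by 4.99 ± 0.81 (adjusted p = 0.00117). Slamf1 rose by 3.18 ± 0.82 (adjusted p = 0.0378), and Cd48 fell by 1.83 ± 0.39 (adjusted p = 0.0107) and Ly6a by 1.27 ± 0.33 (adjusted p = 0.0378). Kit passed with the block (-0.65 ± 0.32, adjusted p = 0.420 without and 0.0186 with it). All of these genes moved the same way in 5 of 5 pairs.

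Of the 28 mitotic genes 11 were higher over all genes and 14 adjusted over the list alone (median 1.31, adjusted p = 1.58e-15, and 0.0109 with an estimated correlation). Of the 28 replication genes 10 and 16 were higher (median 0.73, adjusted p = 9.94e-17, and 0.00744 with an estimated correlation). Aurkb, the kinase of chromosome segregation, had 157.1 ± 22.2 CPM in HSC and 32.9 ± 5.64 CPM in MPP (2.26 ± 0.23, adjusted p = 2.37e-05), and Cdc45, a helicase factor of replication forks, rose by 1.58 ± 0.21 (adjusted p = 0.000176). Cytokine receptors were lower in HSC (median -0.74, 5 of 23 over all genes, 9 adjusted over the list alone, adjusted p = 8.92e-08, and 0.00171 with an estimated correlation). Among them were Ifnar2, a subunit of the type I interferon receptor (-0.99 ± 0.17, adjusted p = 0.00214), and the interferon gamma receptor subunits Ifngr2 (-1.34 ± 0.28, adjusted p = 0.00972) and Ifngr1 (-0.90 ± 0.20, adjusted p = 0.0141). Interferon gamma genes were lower (median -0.69, 6 lower and 1 higher of 31 over all genes, 7 and 1 adjusted over the list alone, adjusted p = 4.40e-05, and 0.00951 with an estimated correlation). Irgm1 stood at -0.83 ± 0.13, and the protease inhibitor Serpina3g was the member that rose (0.84 ± 0.15). MHC class II genes were lower (median -0.70, 3 of 11 over all genes, 6 adjusted over the list alone, adjusted p = 1.89e-05, and 0.00629 with an estimated correlation). So were TNF targets (median -0.44, 3 of 27 and 9 adjusted over the list alone, adjusted p = 0.000185, and 0.00629 with an estimated correlation). Each of these lists moved the same way in 5 of 5 pairs.

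The stem cell list stood higher in HSC (median 0.65, adjusted p = 0.00176, but adjusted p = 0.0731 with an estimated correlation). Over all genes 6 members were higher, among them Gata2 (0.93 ± 0.15, adjusted p = 0.00112), and 3 lower, among them Hlf (-1.42 ± 0.17, adjusted p = 7.41e-05). Adjusted over the list alone the numbers were 8 and 3. Granulocyte and monocyte genes stood lower (median -0.83, 4 of 18 over all genes and 7 adjusted over the list alone, adjusted p = 7.95e-06, and adjusted p = 0.0660 with an estimated correlation). Emb stood at -2.37 ± 0.26, the myeloid factor Spi1 at -1.43 ± 0.17 and Cebpa at -2.99 ± 0.53. Type I interferon genes stood lower (median -0.94, 5 of 36 over all genes and 14 adjusted over the list alone, adjusted p = 6.78e-11, and with an estimated correlation 0.0660 without and 0.0144 with the block). Homing genes stood lower too (4 lower over all genes and 9 adjusted over the list alone, adjusted p = 0.000863, and adjusted p = 0.0686 with an estimated correlation). Oxidative phosphorylation (0.57, adjusted p = 4.21e-06), ribosomal proteins (adjusted p = 0.000600), T and NK markers (-2.77, adjusted p = 0.00483) and dendritic markers (-2.75, adjusted p = 0.0239, and 0.0812 with the block) had adjusted p from 0.162 to 0.740 with an estimated correlation. The stromal and endothelial lists did not pass here (adjusted p = 0.840 and 0.411, with a stromal median of 1.26, or 1.06 with 9 genes at their bounds). The 15 lists not called ran from 0.0693 to 0.945. For red cell, immediate early, p53 and mast cell lists the median, mean and test differed in sign.

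With the block edgeR called 1238 genes (672 higher and 566 lower), 449 of the 451 among them. June alone gave 81 genes and July alone 0 (798 at an unadjusted p under 0.05, against 2026 over all 5 pairs). Genes called were 246, 156 and 152 without replicate numbers 1, 2 and 3 in all groups, and 768 without the 3 libraries least like their groups. With the block they were 541 to 1120 without 1 replicate number in all groups. The 8 lists that held with an estimated correlation kept their direction and preset call in both months, with 0 called in June and 1 in July with an estimated correlation, and held without each single library.

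Among Lepr+ cells, too, HSC carried more mRNA of megakaryocyte and DNA replication genes than MPP. Pf4 stood at 467.2 ± 214.3 CPM in HSC and 30.3 ± 25.1 CPM in MPP and Vwf at 280.1 ± 113.9 and 20.3 ± 3.73 CPM. Flt3 fell from 256.2 ± 88.0 CPM in MPP to 16.4 ± 14.02 CPM in HSC, and stromal genes were lower in HSC as a list. EdgeR called 77 genes, 43 higher and 34 lower.

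Of the 19 megakaryocyte genes 4 were higher over all genes and 13 adjusted over the list alone (median 1.64, adjusted p = 4.97e-18, and 0.00170 with an estimated correlation, 5 of 5 pairs). It was led by Tubb1, the tubulin of platelets (5.49 ± 1.11, adjusted p = 0.0256), Pf4 (3.96 ± 0.63, adjusted p = 0.00651) and Vwf (3.79 ± 0.52, adjusted p = 0.00186). Mfsd2b, the lipid transporter of red cells and platelets, rose from 6.60 ± 4.79 to 90.7 ± 43.5 CPM (3.81 ± 0.62, adjusted p = 0.00759), Gata1 by 3.25 ± 0.63 (adjusted p = 0.0217) and F2rl2, a thrombin receptor, by 2.97 ± 0.59 (adjusted p = 0.0235). Replication genes were higher (median 0.69, 4 of 28 over all genes and 13 adjusted over the list alone, adjusted p = 5.41e-19, and 0.00996 with an estimated correlation, 5 of 5 pairs). Cdc45 stood at 1.49 ± 0.21. Mitotic genes were higher (median 0.91, 5 of 28 and 11 adjusted over the list alone, adjusted p = 4.01e-14, 4 of 5 pairs). They had adjusted p = 0.0369 with an estimated correlation and 0.0528 with the block as well. Aurkb stood at 1.48 ± 0.22 and Birc5 at 1.58 ± 0.24. In the stem cell list 3 of 25 rose over all genes, the oncogene Mycn (1.06 ± 0.17, adjusted p = 0.00708), Gata2 (0.77 ± 0.15) and Ctnnal1. Adjusted over the list alone 8 were higher and 2 lower (adjusted p = 2.72e-05, and 0.0371 with an estimated correlation, 5 of 5 pairs).

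Cd34 fell by 2.00 ± 0.18 (adjusted p = 6.65e-06) and Flt3 by 3.95 ± 0.72 (adjusted p = 0.0149). Cebpa, the factor of granulocytes, fell by 3.32 ± 0.54 (adjusted p = 0.00784), and the leukocyte surface gene Cd53 by 2.63 ± 0.48 (adjusted p = 0.0146), each in 5 of 5 pairs. Spp1, which encodes osteopontin, fell by 2.72 ± 0.59 (adjusted p = 0.0446, and 0.0654 with the block). Slamf1 had 41.4 ± 17.7 CPM in HSC and 5.03 ± 3.02 CPM in MPP (3.03 ± 0.81, adjusted p = 0.124 without and 0.0352 with the block). The stromal list was lower in HSC by a median of -3.09. It had 0 of 24 over all genes and 15 lower and 1 higher adjusted over the list alone (adjusted p = 4.01e-14 and 5 of 5 pairs, and with an estimated correlation 0.0468, or 0.104 with the block). Lymphoid genes stood lower by a median of -1.51, or -1.43 with 1 gene at its bound (3 of 18 over all genes and 6 adjusted over the list alone, adjusted p = 3.83e-08). They had adjusted p = 0.0538 with an estimated correlation and 0.0399 with the block as well. The lists of type I interferon (-0.49, adjusted p = 0.00115), cytokine receptors (-0.50, adjusted p = 0.00361), MHC class II (-0.31, adjusted p = 0.009998), homing (-0.33, adjusted p = 0.0119), fetal stem cells (1.35, adjusted p = 0.0306), oxidative phosphorylation (0.23, adjusted p = 0.00629), ribosomal proteins (adjusted p = 0.00239) and endothelial (-0.88, adjusted p = 0.00316), monocyte (-1.12, adjusted p = 0.00629) and dendritic markers (-1.72, adjusted p = 0.00629) were called with the preset correlation only. They had adjusted p from 0.0508 to 0.698 with an estimated correlation. With the covariate oxidative phosphorylation, ribosomal proteins, endothelial and monocyte markers turned direction (adjusted p = 0.329, 0.338, 0.553 and 0.553). The other 15 lists ran from 0.0657 to 0.915, and for granulocyte and monocyte, TNF, immediate early, p53, glycolysis, T and NK and mast cell lists the median, mean and test differed in sign.

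With the block edgeR called 293 genes (186 higher and 107 lower), 76 of the 77 among them. Without 1 library it called 28 (Lepr+ MPP replicate 2), 32 (Lepr+ HSC replicate 2) or 36 (Lepr+ HSC replicate 4), and 37, 6, 9 and 31 without replicate numbers 1 to 4 in all groups. June and July alone gave 0 and 0 (822 and 839 at an unadjusted p under 0.05, against 1302 over all 5 pairs), and the covariate 2. With the block 65 to 206 genes were called without 1 replicate number in all groups. The 5 lists that held kept direction and preset call in both months, with 1 called in June and 2 in July with an estimated correlation. With an estimated correlation the stem cell list was lost without Lepr+ HSC replicate 1, 3 or 5, Lepr+ MPP replicate 4 or Lepr- HSC replicate 5 (adjusted p from 0.0515 to 0.0948). The mitotic list was lost without Lepr+ HSC replicate 1 or 3 or Lepr+ MPP replicate 4 (adjusted p from 0.0697 to 0.0948) and the stromal list in 14 of the 20 leave-outs (adjusted p from 0.0517 to 0.140).

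**Figure D3:**
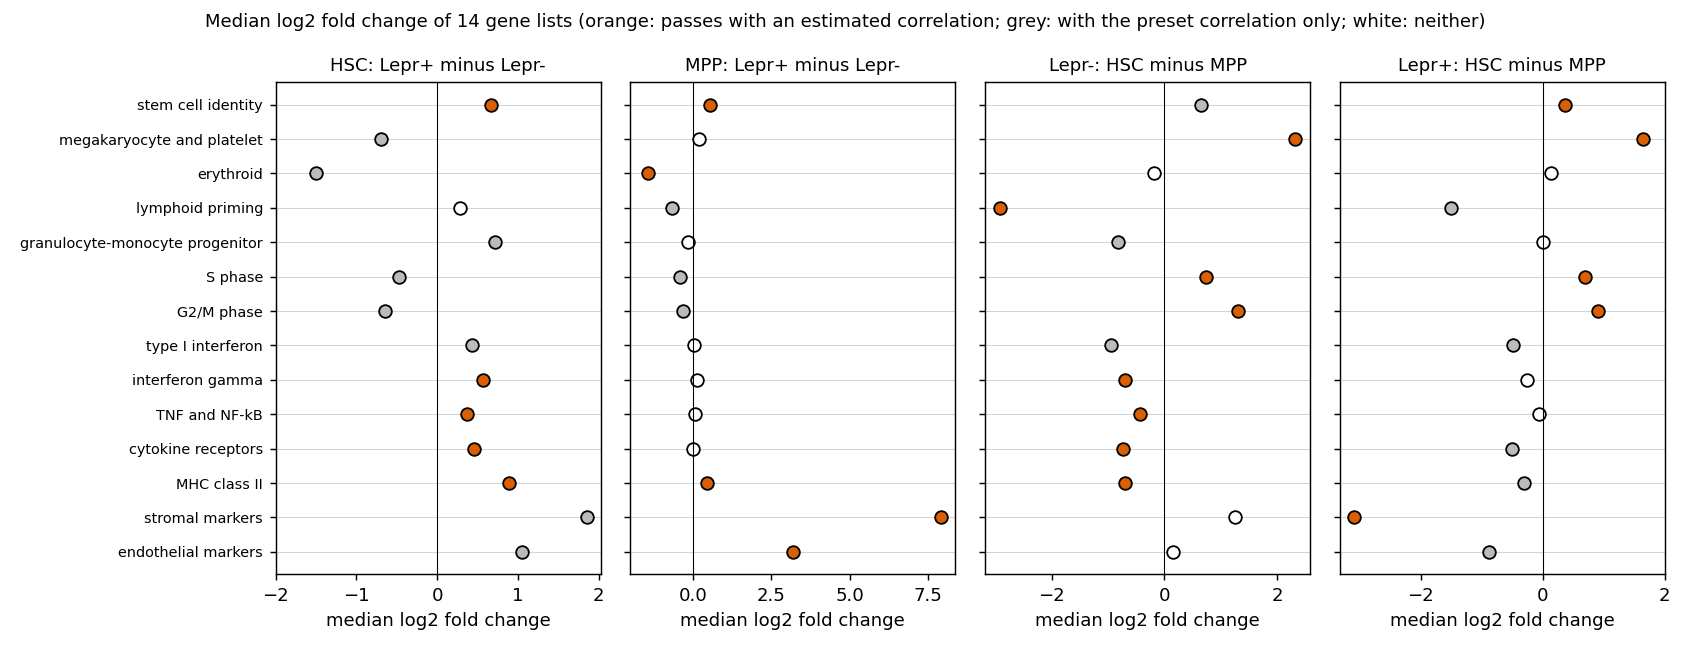
Median log2 fold change of 14 fixed gene lists in the 4 comparisons, coloured by whether the list passed with an estimated correlation, with the preset correlation only or with neither. The stem cell list had medians of 0.67 and 0.55 in Lepr+ against Lepr- HSC and MPP, and the stromal list 1.86 and 7.90.

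The difference between cells sorted with and without Lepr was partly shared by both cell types. Lrg1 and Gpm6a rose in Lepr+ cells of both, and no gene fell in both. Chance would give 0.0281 and 0.000242 genes if genes moved independently. Neither Lrg1 nor Gpm6a was called in MPP with the stromal and endothelial covariate or without the 3 libraries least like their groups. The stromal and endothelial lists also stood higher in Lepr+ cells of both types, in HSC with the preset correlation only. With the block the shared genes were 6, as Cd74, Ndn, Aplnr and Igkc joined them (0.114 by chance). Over 16,509 genes the log2 fold changes correlated at a Pearson r of 0.342 and a Spearman rho of 0.213 across genes, which are not independent replicates, at 0.515 and 0.288 over genes of at least 5 CPM, and at 0.132 and 0.11 with no filter on low counts. In the interaction of Lepr status and cell type edgeR called 0 genes, with 529 at an unadjusted p under 0.05, 0 with the block (830), 19 by DESeq2, 0 by limma voom and 167 by limma voom with the block. That the Lepr+ against Lepr- difference itself differed between HSC and MPP was not shown for any named gene by edgeR.

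Genes of leptin signalling through JAK and STAT, among them Socs3, Stat3 and Jak2, did not pass as a list in any of the 4 comparisons (adjusted p = 0.285, 0.556, 0.776 and 0.915). Socs2, a feedback inhibitor of STAT5 signalling, gave 0.84 and 1.64 in Lepr+ HSC and Lepr+ MPP (adjusted p = 0.700 and 0.131, higher in 5 of 5 pairs of each). Bcl2l1, an inhibitor of cell death, rose in HSC against MPP among Lepr- and Lepr+ cells (1.11 ± 0.26 and 1.38 ± 0.26, adjusted p = 0.0186 and 0.0173). Lists that passed in none of the 4 comparisons were also immediate early genes (adjusted p from 0.201 to 0.690), p53 targets (0.549 to 0.856) and fatty acid oxidation (0.609 to 0.941). The same held for glycolysis without the block (0.0760 to 0.794) and markers of neutrophils (0.476 to 0.971), B cells (0.0832 to 0.971) and mast cells (0.465 to 0.941).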

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

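Of the tests in this part, the relations of Lepr to the stromal score and to Cxcl12 and the 4 counts of splits for lists called with an estimated correlation were chosen only after the results were seen. Among 223 groups of 5 values, 20 had a sample farther from the rest than Dixon's 95% limit of 0.71 allows, where chance would give 11.2, about 1 in 20 groups.

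Lepr+ MPP replicate 4 had 14756 genes at equal depth, against 18680 to 20183 in the other 4 libraries of its group. In mean log2 CPM that library also stood low in the stem cell list (4.943, others 5.738 to 6.022), the G2/M list (2.391, others 4.548 to 5.318) and the fetal stem cell list (-1.727, others 0.407 to 1.045). Lepr- MPP replicate 4 stood low in the stem cell list (4.277, others 5.129 to 5.322), the G2/M list (4.139, others 5.063 to 5.392), and cytokine receptors (3.377, others 4.385 to 4.638). It stood low too in monocyte markers (0.262, others 1.786 to 2.006) and T and NK markers (-1.29, others 1.233 to 1.863), and high in Leprot (139.6 CPM, others 77.42 to 91.08). Leptin and JAK-STAT genes stood low in Lepr+ HSC replicate 5 (5.491, others 6.187 to 6.389) and homing genes in Lepr- HSC replicate 4 (4.276, others 4.722 to 4.845). Glycolysis genes stood low in Lepr+ HSC replicate 1 (6.246, others 6.59 to 6.689). Among single genes in CPM, Cxcl12 stood high in Lepr- HSC replicate 5 (8.158, others 0 to 0.6754) and Adipoq in Lepr- HSC replicate 1 (0.03377, which is 1 count, others 0). Col1a1 stood high in Lepr- HSC replicate 3 (112.4, others 0 to 6.18), Lepr- MPP replicate 5 (8.586, others 0 to 1.403) and Lepr+ MPP replicate 5 (1829, others 14.61 to 58.02). Aurkb stood low in Lepr+ HSC replicate 2 (77.07, others 105 to 116.2) and Lepr- MPP replicate 2 (22.98, others 34.19 to 36.82).

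In 14 lists the Lepr+ against Lepr- difference was not the same in HSC and MPP by camera on the interaction. The Lepr+ against Lepr- difference was lower in HSC for stromal markers (adjusted p = 1.003e-13, and 0.07297 with an estimated correlation), endothelial markers (0.0001809 and 0.1695) and megakaryocyte genes (0.001619 and 0.1711). The same held for monocyte markers (0.002633 and 0.2725) and oxidative phosphorylation (0.03494 and 0.8472). It was higher in HSC for lymphoid genes (0.007991 and 0.4191), granulocyte and monocyte progenitor genes (0.001619 and 0.2348), type I interferon (0.0002654 and 0.3832) and interferon gamma (0.009014 and 0.1383). It was also higher for TNF targets (0.002633 and 0.07297), cytokine receptors (0.003699 and 0.07297), MHC class II (0.02172 and 0.154), glycolysis (0.03494 and 0.4256) and T and NK markers (4.506e-05 and 0.07297). None held with an estimated correlation. Oxidative phosphorylation turned direction without the 3 libraries least like their groups (0.648), and endothelial and monocyte markers with the stromal and endothelial covariate (0.994 and 0.762). Chance was not excluded for these lists, since 5 of 100 splits gave as many lists (14, highest other 17), nor for the genes at an unadjusted p under 0.05, where 46 of 100 did (529, highest other 3283).

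For other splits of the 10 libraries of a comparison, 100 of the 126 were drawn, the real one included. These splits ignore the pairing by replicate number, so a low share of them does not exclude chance for paired samples. The share with as many called genes was under 0.05 in each comparison. Lepr+ against Lepr- HSC had 17 genes (highest other 241, 2 splits with as many) and Lepr+ against Lepr- MPP 33 (highest other 1, 1 split). HSC against MPP had 451 genes among Lepr- cells (highest other 0, 1 split) and 77 among Lepr+ cells (highest other 2563, 2 splits). The splits with 241 and 2563 genes put replicates 1 and 3 of both groups on the same side and so followed a structure of the samples by replicate number. With the block the real splits gave 169 and 293 genes. Among the 16 splits that part all 5 pairs, the real one included, which are too few for a share under 0.05, the highest others were 0, 0, 0 and 1 genes in the 4 comparisons. For the called lists the share of the same free splits was under 0.05 in Lepr+ against Lepr- HSC (17 lists, highest other 17, 2 splits). The same held in HSC against MPP among Lepr+ cells (16, highest other 16, 2 splits). The share was not under 0.05 in Lepr+ against Lepr- MPP (12, highest other 14, 7 splits) or HSC against MPP among Lepr- cells (16, highest other 20, 9 splits). For lists called with an estimated correlation the share was under 0.05 in each of the 4 comparisons. In the order given for genes they had 5, 5, 8 and 5 lists (highest others 1, 2, 1 and 2, and 1 split each). For the called lists with the block, the 16 swaps within pairs are too few for a share under 0.05, with 16, 15, 15 and 16 lists and highest others of 17, 13, 16 and 13. In Lepr+ against Lepr- HSC and in HSC against MPP among Lepr- cells another swap thus gave more lists than the real labels. In Lepr+ against Lepr- HSC the other free split with 17 lists parted all 5 pairs, as the real one does. For the genes called with the block, the 16 swaps within pairs are too few for a share under 0.05. They had 169, 17, 1238 and 293 genes, highest others of 0, 0, 0 and 5, and 1 swap with as many in each.

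Lepr transcripts were uneven between libraries sorted for the receptor, from 0.0759 to 9.36 CPM in Lepr+ HSC. RNA of marrow stromal cells, the main Lepr-bearing cells of marrow, is a candidate source, although the Sca-1 and c-Kit gates should remove such cells; within the Lepr+ groups Lepr had a mean Spearman correlation of 0.15 with the stromal score (0.3 in HSC and 0 in MPP, exact permutation p = 0.735, adjusted p = 0.842 over 5 relations). With Cxcl12 alone, a stromal gene chosen after its values were seen, the mean correlation was 0.95 (0.9 in HSC and 1 in MPP, p = 0.0013, adjusted p = 0.0078 over 6 relations), which goes with that source, while Lepr counts per 100 Cxcl12 counts ran from 3.02 to 7.91 in MPP and more widely, from 1.23 to 21.9, in the 4 HSC libraries with enough counts. The 24 stromal genes were listed before the test, 8 of them reached 5 CPM in Lepr- cells and 0 stood in another list; the most abundant, Apoe and Igfbp4, had 1050 and 276.4 CPM in Lepr- HSC and 970.1 and 324.4 CPM in Lepr+ HSC, while Cxcl12 had 1.80 and 30.8 CPM. Low library complexity gave -0.5 (exact permutation p = 0.192, adjusted p = 0.321), and as 1 gene picked from its values decides nothing, stromal RNA, complexity and Lepr expression by the sorted cells cannot be told apart with 5 libraries a group.

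The stem cell list was higher and the red cell list lower in Lepr+ HSC. With the stromal and endothelial mean as a covariate both stayed called, the stem cell list at an adjusted p of 1.894e-06 (median 0.54 against 0.67 without it) and the red cell list at 3.251e-07 (-2.13 against -1.50), and with genes detected at equal depth as a covariate at 8.269e-09 (0.79) and 6.935e-05 (-1.71). With an estimated correlation as well, the stem cell list stayed at 0.0190 and 0.00264 and the red cell list, not called with no covariate (0.112), had 0.0343 and 0.135. For the stem cell list these values argue against library complexity, or RNA tracked by the stromal and endothelial mean, as the whole source. The covariate slopes were fitted over all 20 libraries. In Lepr- cells 8 of 24 stromal and 9 of 18 endothelial genes already reached 5 CPM. That mean is thus an imperfect measure of foreign RNA, and such RNA is not excluded. For the red cell list the values with covariates decide nothing, as its call without a covariate was already lost with an estimated correlation. RNA of antibody-making or other marrow cells was not tested. A difference between Lepr+ and Lepr- stem cells, which the sort gives, stays open as a hypothesis.

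Cell cycle lists were higher in HSC than in MPP, while stem cells are known as slow to divide. With genes detected as a covariate the mitotic list among Lepr- cells stayed called (median 1.38 against 1.31 without it, adjusted p = 1.724e-17, and 0.00616 with an estimated correlation), which argues against complexity as the whole source, although within the HSC groups the mitotic score rose with genes detected (mean Spearman correlation 0.9, exact permutation p = 0.0043, adjusted p = 0.0215). Megakaryocyte-primed cells in the HSC gate are a candidate explanation, but the mitotic score had a mean correlation of -0.1 with the megakaryocyte score (exact permutation p = 0.842, adjusted p = 0.842), within its spread, so that source and a difference in cycling between the gates cannot be told apart. With the red cell score the mean correlation was 0.75 (exact permutation p = 0.0336, adjusted p = 0.084).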

How the results depend on the processing

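Of the tests in this part, those with counts thinned to equal depth, without the 3 libraries least like their groups, with the stromal and endothelial covariate, with the block beside an estimated correlation, all further settings of the block fit and lists by month or without single libraries were chosen only after the data were seen. Of 144 calls of named genes, 143 were kept with RLE factors, 144 by DESeq2, 128 by limma voom with quality weights, and 129 with no filter. It was 134 with thinned counts, 131 with the block, 102 without the 3 libraries and 81 with the covariate, and none changed direction. Stromal and endothelial genes make up the covariate, so the loss of their own gene and list calls with it was built in. With only the 2 groups compared 74 of 136 were kept, without a replicate number 42 to 84, in June alone 24 and in July alone 0 of 143. Of 75 list calls, 75 were kept with RLE factors, 70 with thinned counts, 73 with the block, 65 without the 3 libraries, 50 with the covariate, 36 by fry and 23 with an estimated correlation. With the block the 2 calls lost were granulocyte and monocyte progenitor genes in Lepr+ HSC (0.0560) and dendritic markers among Lepr- cells (0.0812), and 3 lists were gained in Lepr+ MPP, quiescence (0.0495), interferon gamma (0.0495) and glycolysis (0.0442).

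Counts of called genes are given for Lepr+ against Lepr- HSC, Lepr+ against Lepr- MPP, and HSC against MPP among Lepr- and among Lepr+ cells, in that order. DESeq2 called 181, 213, 844 and 343, and limma voom with quality weights 10, 304, 1890 and 264. The block called 169, 17, 1238 and 293, and voom with the block 1762, 841, 4636 and 1747. June alone gave 0, 0, 81 and 0 and July alone 0, 0, 0 and 0 by edgeR, from fewer samples. There were 1031, 556, 1441 and 822 and with 426, 367, 798 and 839 at an unadjusted p under 0.05. With only the 2 groups compared the counts were 0 (731 at that level), 16, 531 and 4. Without the 3 libraries least like their groups they were 8, 0, 768 and 59, and with the covariate 6, 1, 454 and 2. For the interaction DESeq2 called 19 genes and voom with the block 167. In the block fit the covariate left 63, 0, 1277 and 2, and without the 3 libraries 143, 2, 1977 and 180. For Lepr+ against Lepr- MPP RLE factors gave 28, a filter of 5 CPM in 5 libraries 36 and thinned counts 37. Leaving out single libraries or replicate numbers gave 0 to 24, 0 to 49, 152 to 556 and 6 to 97 genes, and 0 to 0 for the interaction. With the block it gave 23 to 88, 0 to 11, 541 to 1120, 65 to 206 and 0 to 0. The correlation of the 2 Lepr+ against Lepr- differences across genes fell to 0.132 with no filter on low counts. For these changes the cause was not tested.

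Slamf1 had a log2 fold change near 0 between Lepr+ and Lepr- cells and turned positive in HSC by voom with the block (0.0913), without Lepr+ HSC replicate 2 (0.00608) and without replicate number 2 (0.0606). In MPP it turned positive with RLE factors (0.00703), the 5 CPM filter (0.00344), DESeq2 (0.00425), voom (0.0747), the block (0.0139), voom with the block (0.166) and June alone (0.329). It did so without Lepr- MPP replicate 2 (0.370), Lepr- MPP replicate 3 (0.167), Lepr+ MPP replicate 4 (0.289), replicate number 2 (0.347) or the 3 libraries (0.354). Slamf1 ranged to its lowest values of -0.44 in HSC without replicate number 3 and -0.33 in MPP without Lepr- MPP replicate 4. With the covariate the direction turned in Lepr+ MPP for fetal genes (adjusted p = 0.857) and monocyte markers (0.189). It turned in HSC against MPP among Lepr+ cells for oxidative phosphorylation (0.329), ribosomal proteins (0.338), endothelial markers (0.553) and monocyte markers (0.553), and in the interaction for endothelial (0.994) and monocyte markers (0.762). Without the 3 libraries it turned for mitochondrially encoded genes in Lepr+ MPP (0.0351) and for oxidative phosphorylation in the interaction (0.648). For all of these the cause was not tested. With the covariate the stromal and endothelial lists in Lepr+ MPP had adjusted p of 0.263 and 0.635 and the stromal list among Lepr+ cells 0.0932. As the covariate is the mean of these same genes, a loss or turn of either list with it tests nothing. Without the 3 libraries the class II list in Lepr+ MPP had 0.0750. The lowest library total of 9,532,993 counts limits what can be seen of rare transcripts such as Lepr.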

Other observations

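No tests were added for this part, and its genes beyond the naming rule were chosen after their values were seen. Antibody genes were present in the Lepr+ groups and uneven between libraries. Igkc, the kappa light chain, had 0.261, 106.6 ± 153.6, 0.355 and 864.7 ± 1513 CPM in Lepr- HSC, Lepr+ HSC, Lepr- MPP and Lepr+ MPP, and Jchain, which joins antibody units in plasma cells, 1.08, 48.1 ± 90.0, 0.239 and 253 ± 363 CPM. Ighm, the heavy chain of IgM, had 3.83, 70.2 ± 128, 119 ± 63.8 and 483 ± 849 CPM. Trbc2, a constant segment of the T cell receptor, had 1.92 ± 1.15 CPM in Lepr- MPP and 0.0457 CPM in Lepr+ MPP (adjusted p = 0.304, lower in 5 of 5 pairs).

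Imprinted H19, a non-coding RNA of fetal tissues and stem cells, had 161 counts in Lepr- HSC and 0 in Lepr- MPP, at least 62.1-fold more (adjusted p = 0.0150, 5 of 5 pairs). Cdkn1c, the imprinted cell cycle inhibitor p57, gave a log2 fold change of 1.25 in Lepr+ against Lepr- HSC (adjusted p = 0.144, and 0.0481 with the block) and of 1.40 in MPP (adjusted p = 0.0861), higher in 5 of 5 pairs of each. The immediate early gene Egr1 rose in HSC against MPP among Lepr+ cells by 1.62 ± 0.34 (adjusted p = 0.0341, 5 of 5 pairs). The enzyme gene Ldha rose in HSC against MPP among Lepr- cells by 1.04 ± 0.27 and the fatty acid carrier gene Fabp5 by 1.14 ± 0.22 (adjusted p = 0.0398 and 0.00588, 5 of 5 pairs each).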
